A study of Myxococcus xanthus DK 1622 with 14 samples.

How the data were processed

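The data are ChIP-seq profiles of Myxococcus xanthus DK 1622 with a monoclonal antibody against the HA tag. Per the labels' protocols, strains with copper-dependent native parB and vanillate-dependent HA-parB were grown with copper, washed and kept for 24 h with vanillate. At an OD550 of 0.5 the cells were crosslinked with 1% formaldehyde for 10 min at room temperature and 30 min on ice. DNA was sheared to an average of 0.2 to 0.5 kbp, 2% of each pre-cleared lysate was kept as input, and the rest was precipitated. Groups and replicate numbers were taken from the sample titles: the untagged depletion strain and HA-ParB WT, Q52A, E93A and R95A with 2 ChIP libraries each, and 1 input per HA-ParB protein. All 14 libraries were used.

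Per the submitters' processing notes, bcl2fastq, FastQC 0.72 and Bowtie2 2.4.2 were used; the genome build is not given in the sources used here. The deposited table gives signal in 182796 windows of 50 bp over a chromosome of 9139763 bp, with the name of the overlapping gene, and per the file headers the values are normalized as RPM. Each column sums to about 1.88 M, as it would if a read were counted in each window it overlaps (1.88 windows per read on average), a reading that the file does not state. The values were therefore treated as signal on a scale that is the same in all libraries and not as RPM in the strict sense. The design had assumed RPM; the test chosen for it, limma on log values, also suits this signal. Every value was a whole multiple of what 1 read is worth in its library within 0.05 reads (100% of values), which gave back whole reads. The depth of each library follows from this step if values are per 1 M reads of the library, and rests on that reading. The ChIP libraries held 17.8 and 21.3 (untagged), 23.0 and 16.9 (WT), 29.2 and 25.1 (Q52A), 22.1 and 23.5 (E93A) and 25.0 and 24.1 (R95A) M reads, and the inputs 22.0 (WT), 25.2 (Q52A), 5.95 (E93A) and 10.6 (R95A) M. Counting error was smaller than the spread between replicates: over bins of 1 kb the chi-square per degree of freedom of the replicate pair was 3.18 for Q52A, 33.0 for R95A, 77.6 for the untagged control, 120 for E93A and 137 for WT. No pair differed by as little as sampling noise, as 1 library deposited again would, so no libraries were merged; this does not show that they came from separate cultures.

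Gene names are those of the table: a gene is a run of windows with 1 name, and each rRNA operon is the unannotated gap in which the RefSeq gene order places it. The RefSeq gene table of assembly ASM1268v1 was used only for names and for which genes neighbour each other; 6474 of the 7250 features matched it. No genome sequence was used here, so parS sites were not searched for and no measure that needs their positions was computed.

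Windows were averaged into 1-kb bins and into genes. Bins and genes with a mean over all 14 libraries under 1 RPM were left out, which kept 9105 of 9140 bins and 7229 genes. Values were tested as log2(RPM + 1) with limma 3.58.1 (lmFit, contrasts, eBayes with trend; R 4.3.3) in 1 fit of all 10 ChIP libraries, with the group as the only term and Benjamini-Hochberg adjustment over bins or genes. Log2 differences, and the folds of bins and genes taken from them, are on this scale, which understates changes at low values; folds between levels of regions, bands and domains are plain ratios with no pseudocount. A bin was called enriched over the untagged control at an adjusted p under 0.05 and a log2 difference of at least 1, and different between proteins at an adjusted p under 0.05. The fit has 5 residual degrees of freedom. On values as deposited limma set its prior degrees of freedom to infinity, so that the variance of each bin or gene followed the trend alone and p-values became extremely small; after background scaling (each library divided by its own median over bins or genes and multiplied by the mean of these medians) the prior degrees of freedom were 7.42 for bins and 6.99 for genes. Except under the replicate block, adjusted p-values quoted for single genes are therefore those after background scaling, while counts are given on both scales. As deposited, the median log2 difference of all bins from the untagged control was 0.03 for WT, -0.93 for Q52A, -0.37 for E93A and 0.48 for R95A, and from WT -0.96 for Q52A, -0.41 for E93A and 0.45 for R95A. Standard errors are from limma on values as deposited.

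The apex is the 1-kb bin with the largest mean log2 difference of the 4 HA-ParB groups over the control, and the core is the interval around it in which the mean profile exceeds 0.5 of its apex height above the median. The core and the bins 0 to 10 kb and 10 to 50 kb beyond it on either side were tested with fry from limma (two-sided, adjusted over 5 sets and 10 contrasts). The par_and_origin, segregation_and_division, highly_transcribed and rRNA gene lists were tested in the same way, with 12, 13, 23 and 4 members found, and their members were also counted with the p adjusted over the list alone. The fry test asks whether a set moves on balance in 1 direction, and its mixed p, given where named, whether its members change in either direction; neither compares the set with other genes. Each library was also summarised by the share of its signal within 100 kb of the apex, its highest bin over the median, the stretch above 2 times the median with gaps up to 2 kb closed, and the share of its excess signal within 50 kb of the core that lies 10 to 50 kb outside it. These were compared among the 8 HA-ParB libraries by an exact permutation test of the F statistic of the log2 measure (log2(kb + 1) for the stretch), adjusted over the 4 measures. Inputs have 1 library per protein and no test.

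Groups, tests, thresholds, gene lists, the rule for named genes and the alternatives not marked as added were fixed before the data were examined. Named are the apex, members of the lists, up to 10 enriched regions over 100 kb from the apex that are higher in all HA-ParB than in all untagged libraries, and up to 10 genes in each direction per contrast with the largest log2 difference among those past the threshold whose groups do not overlap. Levels over parB, at MXAN_0018 and MXAN_0019, beside the left end of the Q52A stretch and in the distal domains were chosen for description after their values were seen, as was the rule that defines these domains. The values of 1 of these domains are not reported here. Background scaling was among the alternatives chosen at the outset, but the weight given to it was decided after the shift of the medians was seen. TMM, background scaling with a library left out, gaps of 10 kb and division by R95A were added after the data were seen.

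The fits were tested on simulated counts over 9105 bins. They were drawn for all 10 libraries at their depths from the mean profile of the R95A libraries, with a dispersion of 0.01, which is a choice and not an estimate from these data, and 200 bins were changed in Q52A alone. For Q52A minus WT limma recovered 71.6% of the bins changed 1.5-fold, 98.5% of those changed 2-fold and all 66 changed 4-fold, with 2.17% of its calls on unchanged bins. With edgeR 4.0.16 the figures were 73.1%, all 67 and all 66, with 2.15%. The simulated libraries hold no ParB peak and no shift of the medians, which was -0.96 for the real Q52A minus WT. These rates therefore need not hold for the real counts. Alternatives were other pseudocounts (0.1 and 5 RPM), no filter, bins of 500 bp and 5 kb, eBayes without trend, a replicate block, division by the input, background scaling, edgeR's quasi-likelihood test on the whole reads of every other window with library totals or TMM, other definitions of background and stretch, and leaving out each library in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.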

Results

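The series followed ParB on the chromosome of Myxococcus xanthus DK 1622, a soil bacterium with a circular chromosome, by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against the HA tag. ParB is the DNA-binding protein of the ParABS chromosome segregation system. It loads at parS sites near the replication origin and slides along the neighbouring DNA as a CTP-dependent clamp. All strains descend from a strain whose native parB is expressed only with copper. The HA-tagged protein was made from a vanillate-dependent promoter as the wild type (WT) or with the exchange Q52A, E93A or R95A, and native ParB was depleted for 24 h before crosslinking. The depletion strain with no tagged protein was the background control, written untagged below. The stated aim concerns the part that CTP hydrolysis by ParB plays in the partition complex, so the comparisons ask where each exchanged protein sits relative to the wild type.

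Each of the 5 ChIP groups had 2 samples, and each of the 4 HA-ParB proteins had 1 total input that covers both of its samples. As recovered from the steps of the values, the 10 ChIP libraries held 16.9 M to 29.2 M reads and the 4 inputs 5.95 M to 25.2 M. Values are in the normalized read unit of the file (RPM) per 50-bp window, given as mean ± SD with n = 2 per group unless stated. A level is a value divided by the median of the same library over the chromosome. The labels do not say that the samples came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. Coordinates are those of the deposited table on a chromosome of 9139763 bp, whose build is not given in the sources used here.

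The first comparison set each tagged protein against the untagged control. Wild-type HA-ParB was concentrated on a 17-kb core (9099001 to 9116000) that holds bacM (MXAN_7475, a bactofilin cytoskeletal protein), parB (MXAN_7476), parA (MXAN_7477, the partition ATPase), gidB (a 16S rRNA methyltransferase) and part of gidA (a tRNA modification enzyme). The core stood at 275 ± 153 times the chromosome median with WT (383 and 167 in replicates 1 and 2), 451 ± 21.4 times with Q52A and 329 ± 116 times with E93A, against 3.42 ± 0.53 times in the untagged control. HA-ParB R95A stood at 2.31 ± 0.20 times there and was not told apart from the control (median log2 difference 0.10, adjusted p = 0.703). The highest 1-kb bin, 9110001 to 9111000 over MXAN_7485 and MXAN_7486, held 4343 ± 1690 RPM with WT, 1887 ± 74.7 with Q52A, 2705 ± 735 with E93A, 33.4 ± 4.06 with R95A and 41.7 ± 2.49 in the control.

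The apex, defined as the 1-kb bin with the largest mean log2 difference of the HA-ParB groups over the control, was 9114001 to 9115000, over MXAN_7492 and gidB. It held 893 ± 359 RPM with WT, 898 ± 19.7 with Q52A, 976 ± 224 with E93A, 11 ± 1.61 with R95A and 7.96 ± 2.45 in the untagged control. On the log2(RPM + 1) scale these were 97.6-fold, 102-fold, 110-fold and 1.36-fold differences from the control. Because enriched libraries lose background reads, the fit was also made after background scaling, in which each library is divided by its own chromosome median and multiplied by the mean of those medians. The adjusted p at the apex was then 0.0019 for WT, 3.4e-06 for Q52A, 1.5e-05 for E93A and 0.95 for R95A (limma). As this bin was chosen on the same differences in the same libraries, its folds and p-values are no independent test of enrichment.

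Of 9105 1-kb bins tested, 29 were enriched with WT, all within 100 kb of the apex. Q52A enriched 191 bins, of which 149 lay within 100 kb, and E93A enriched 148, of which 124 lay within 100 kb. The corresponding counts after background scaling were 29, 250 and 218. R95A passed in 210 bins, of which 7 lay within 100 kb, but in 1 bin after background scaling. Left-out libraries moved the R95A count to 2 without untagged replicate 1, 2208 without untagged replicate 2, 1163 without R95A replicate 1 and 1 without R95A replicate 2. The WT count became 266 without untagged replicate 2. After background scaling the counts without that library were 69 for WT and 7 for R95A.

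Bins enriched as deposited, with the R95A bins that background scaling removed, merged into 176 regions. Of the 176, 174 lay more than 100 kb from the apex. Among these, 8917001 to 8918000 (MXAN_7301 and MXAN_7302) was the one higher in all 8 HA-ParB libraries than in both untagged libraries. It held 2.63 ± 1.10 RPM in the control, 4.69 ± 0.65 with WT, 4.62 ± 0.14 with Q52A, 4.06 ± 0.06 with E93A and 6.29 ± 1.34 with R95A. The inputs there held 9.60 to 16.6 RPM. The mean chromosome median was 5.93 RPM in the control, 6.10 with WT, 2.63 with Q52A, 4.38 with E93A and 8.67 with R95A. Only the Q52A mean thus stood above the median in this region. Only R95A passed the enrichment test in it (log2 1.03, and 0.56 after background scaling).

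**Figure D1:**
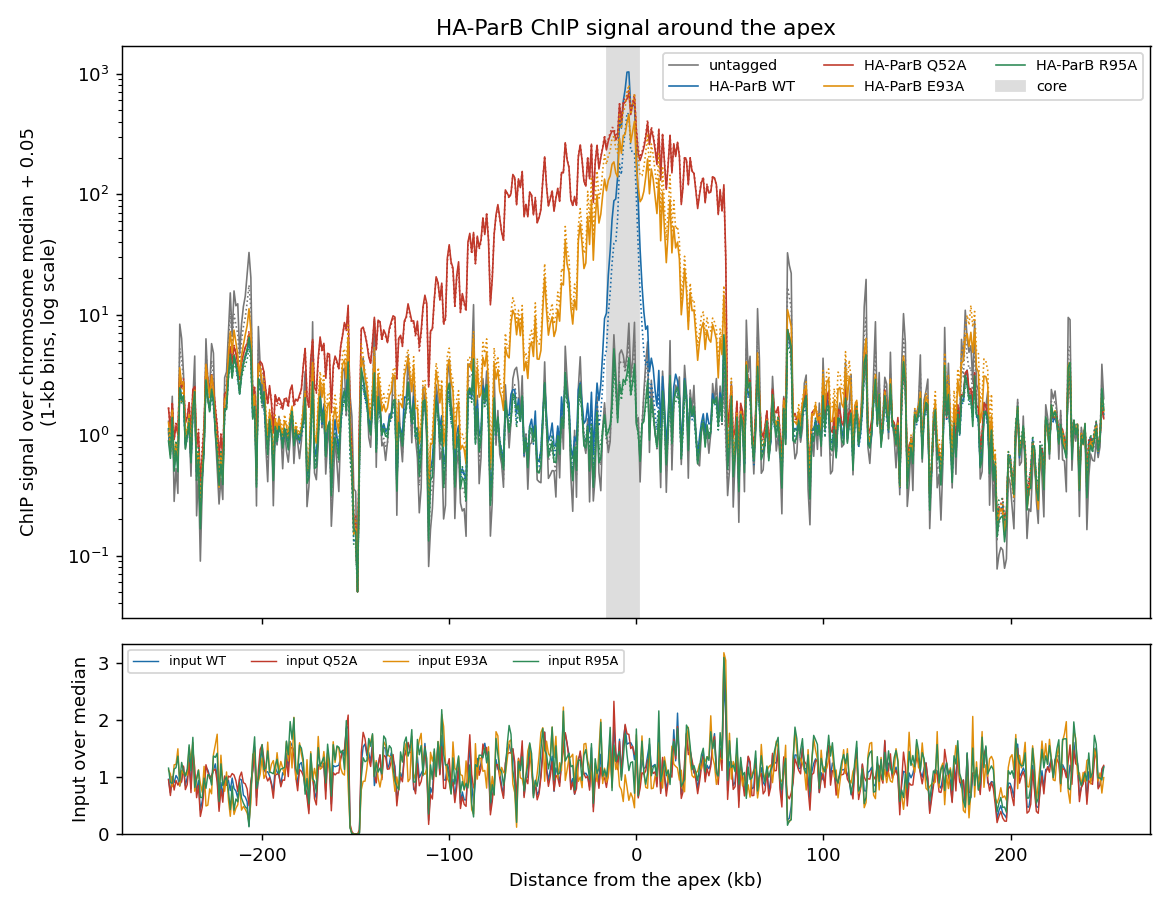
Level of each library over its own chromosome median (log axis, 1-kb bins) by distance in kb from the apex, with solid and dotted lines for replicates 1 and 2, the 17-kb core shaded and the 4 inputs in the lower panel. The core averages 275 times the median with WT, 451 times with Q52A and 329 times with E93A, and the Q52A signal still stands at 15.4 times the median 75 to 100 kb to the left of the core, where WT stands at 0.994 times.

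Against the wild type, HA-ParB Q52A spread over a much longer stretch on both sides of the core. From 20 to 30 kb to the left of it the level was 140 ± 0.80 with Q52A and 1.38 ± 0.17 with WT (102-fold), and over the same distance to the right it was 164 ± 2.20 and 1.57 ± 0.19. The gene dnaA, which encodes the replication initiator, held 558 ± 1.46 RPM with Q52A and 15.0 ± 0.20 with WT, a log2 difference of 5.13 ± 0.28 (SE). The flanking genes trmE (tRNA modification GTPase; 328 ± 1.89 against 4.97 ± 0.0231 RPM), rnpA (RNase P protein; 692 ± 21.6 against 13.1 ± 0.793) and rpmH (ribosomal protein L34; 476 ± 18.1 against 8.58 ± 0.802) moved the same way. Within the core the proteins were closer, and gidA at its right border held 481 ± 16.8 RPM with Q52A and 153 ± 59.4 with WT.

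The Q52A level fell off slowly to the left, to 58.3 ± 0.51 at 50 to 75 kb and 15.4 ± 0.40 at 75 to 100 kb. To the right it was 82.6 ± 0.41 at 30 to 50 kb and 1.61 ± 0.04 at 50 to 75 kb, next to 1.23 ± 0.07 with WT. The largest differences were at MXAN_7464 (530 ± 3.03 against 8.13 ± 0.906 RPM, 133-fold after background scaling, adjusted p = 2.7e-09). Next came MXAN_7508, MXAN_7465 (a voltage-gated chloride channel), trmE, MXAN_7507, MXAN_7500, MXAN_7510 (yidD), MXAN_7503, MXAN_7501 (an ArsR-family regulator) and sppA at 9123451 (a signal peptide peptidase), each 118-fold to 129-fold after background scaling. All 40 bins 10 to 50 kb to the left of the core and 37 of 41 to the right were higher with Q52A. The fry median log2 on the left was 5.27 (adjusted p = 2.01e-06). Over the core itself 3 of 17 bins were higher with Q52A. The fry test called no shift of the core in 1 direction (median log2 -0.17, mean 0.31, adjusted p = 0.386) but a change in either direction (adjusted p = 6.41e-06), and background scaling turned the median to 1.04 (adjusted p = 0.0315).

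Away from the core nearly all Q52A values were lower than WT values as deposited, and the median log2 difference over all bins was -0.96. The genes with the largest deficits included ihfB at 4081851 (integration host factor beta; 2.41 ± 0.00464 against 10.0 ± 1.01 RPM), MXAN_1054 and MXAN_6077. These 3 still passed after background scaling, with log2 differences of -0.74, -0.45 and -0.46 and adjusted p of 0.032, 0.016 and 0.028. Of the other 7 named by the same rule, among them rpsL (ribosomal protein S12), none passed after background scaling (adjusted p 0.073 to 1). In total 203 bins were higher with Q52A and 8659 lower. Background scaling changed this to 338 and 6, with 147 of the higher bins within 100 kb of the apex. Those 6 lower bins became 43 and 45 without untagged replicates 1 and 2, and 1 without either Q52A library. They became 0 without WT replicate 1, where limma had 493 bins at an unadjusted p under 0.05 and edgeR with TMM on all libraries called 9.

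The par_and_origin list, fixed from annotation beforehand, holds parA, parB and 10 genes known to lie near bacterial origins. With Q52A, 7 of its 12 members were higher than with WT and 3 lower (adjusted over the list alone, 7 and 3; fry median log2 1.35, adjusted p = 7.86e-05). After background scaling 7 were higher and none called lower (limma; adjusted over the list alone, 9 and 0; median 2.55, adjusted p = 0.000131). The 3 lower members were dnaN, recF and gyrB, which lie more than 300 kb from the apex in this chromosome. The gene dnaN held 4.41 ± 0.0709 RPM with Q52A and 11.1 ± 1.35 with WT. The segregation_and_division, highly_transcribed and rRNA lists had medians of -1.03, -1.10 and -0.84 as deposited, and of -0.09, -0.09 and -0.12 after background scaling, when none of their tests passed.

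HA-ParB E93A also spread beyond the wild-type domain, with a steeper decline than Q52A. From 20 to 30 kb beyond the core the level was 19.5 ± 3.75 on the left (14.2-fold over WT) and 19.2 ± 3.45 on the right (12.2-fold), and at 30 to 50 kb it was 8.39 ± 1.37 and 6.17 ± 0.91. The gene dnaA held 112 ± 4.29 RPM with E93A and 15.0 ± 0.20 with WT (9.69-fold after background scaling, adjusted p = 2.8e-05), and trmE held 176 ± 32.3 and 4.97 ± 0.0231 RPM (40.0-fold, adjusted p = 1.7e-07). The largest differences were at MXAN_7499 (609 ± 137 against 12.8 ± 1.78 RPM; log2 5.45 ± 0.29 SE) and sppA (500 ± 109 against 10.7 ± 1.63). They were followed by MXAN_7500, MXAN_7465, MXAN_7464, MXAN_7497 (an M16B peptidase), MXAN_7501, MXAN_7502, MXAN_7503 and MXAN_7507, which were 43.4-fold to 54.8-fold higher after background scaling.

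All 40 bins 10 to 50 kb to the left of the core were higher with E93A than with WT (fry median log2 2.69, adjusted p = 1.11e-05), as were 35 of 41 on the right. Over the core 2 of 17 bins were higher. The fry test called no shift in 1 direction there (median log2 0.12, adjusted p = 0.203) but a change in either direction (adjusted p = 9.04e-05). At gidA the log2 difference was 1.60 ± 0.30 (SE), and it was 1.20 and no longer passed without WT replicate 2. In the par_and_origin list 6 of 12 members were higher (adjusted over the list alone, 7; median 1.34, adjusted p = 0.000161). After background scaling there were 6, or 8 adjusted over the list alone, with a median of 1.80 and adjusted p = 0.000579. The highly_transcribed list was lower as deposited (median -0.43, 1 of 23 members, or 16 adjusted over the list alone, adjusted p = 0.0196) but not after background scaling (median -0.02). The segregation_and_division list (median -0.35, adjusted p = 0.0552) and the rRNA list (median -0.28, adjusted p = 0.24) did not pass the fry test for a shift in 1 direction. The first of them passed that for a change in either direction (adjusted p = 0.0134), but not after background scaling (adjusted p = 0.0992).

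In total 167 bins were higher and 37 lower with E93A than with WT, and 368 and 4 after background scaling. Of the higher bins, 111 and 131 lay within 100 kb. The gene MXAN_2748, a glutamine amidotransferase domain protein, was the one named gene that was lower both as deposited (log2 -0.77) and after background scaling (-0.40, adjusted p = 0.0073). It lost its call without WT replicate 2 (-0.68) and without E93A replicate 2 (-0.74). The 37 lower bins became 5073 and 5086 without untagged replicates 1 and 2, 5067 without WT replicate 1, and 2379 without E93A replicate 1. They became 1 without E93A replicate 2, 2 without either Q52A library and 7 without either R95A library, and 0 without WT replicate 2 (limma; 447 bins at an unadjusted p under 0.05; 559 with edgeR on all libraries). After background scaling the higher count was 220 without WT replicate 2 and 228 without E93A replicate 2. The lower count was 148 and 147 without untagged replicates 1 and 2 and 1 without WT replicate 2 or either Q52A library. It was 0 without WT replicate 1 or either E93A library (limma; 596, 740 and 722 bins at an unadjusted p under 0.05; 0 with edgeR and TMM on all libraries).

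**Figure D2:**
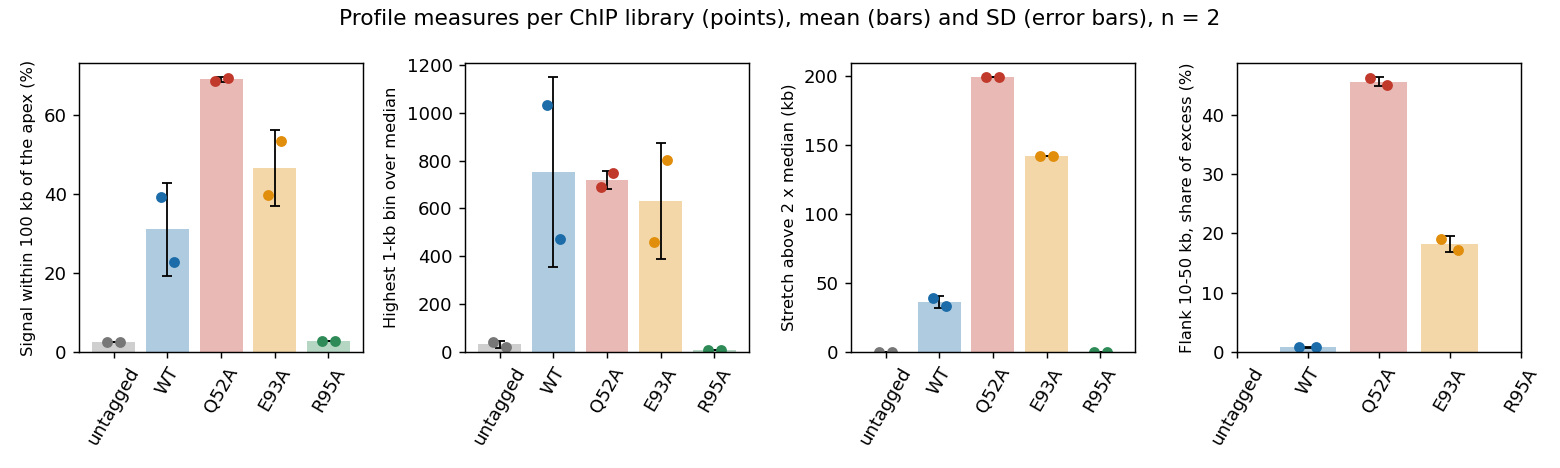
Share of signal within 100 kb of the apex (percent), height of the highest 1-kb bin over the chromosome median, length of the stretch above 2 times the median (kb) and share of excess signal 10 to 50 kb outside the core (percent), with points for libraries, bars for means and error bars for the SD (n = 2); the last panel leaves out the untagged control and R95A, which have little excess signal. Q52A holds 69.0% of its signal within 100 kb, E93A 46.5%, WT 31.0%, R95A 2.62% and the control 2.41%.

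The group means of share, stretch and flank share were highest with Q52A among WT, E93A and Q52A and lowest with WT, and those of the height were not in that order. The share of signal within 100 kb of the apex was 31.0 ± 11.8% with WT (39.3% and 22.7% in replicates 1 and 2) and 69.0 ± 0.60% with Q52A. It was 46.5 ± 9.61% with E93A (39.8% and 53.3%) and 2.62 ± 0.0038% with R95A. It was 2.41 ± 0.03% in the untagged control and 2.43% to 2.67% in the inputs. The stretch around the apex above 2 times the median was 36 ± 4.24 kb with WT, 199 kb in both Q52A libraries (8967001 to 26000 across the numbering origin) and 142 kb in both E93A libraries (9024001 to 26000). The left end with Q52A borders 6 kb (8961001 to 8967000) in which all 4 inputs stood at 0.176 times their medians or less, and Q52A stood at 8.01 and 7.72 times in the 5 kb beyond, so this end need not be that of the signal. Of the excess signal within 50 kb of the core, 0.78 ± 0.09% lay 10 to 50 kb outside it with WT, 18.2 ± 1.37% with E93A and 45.7 ± 0.79% with Q52A. With R95A, which has little excess signal to divide, it was 52.2% and 50.4%, next to 43.1% and 38.3% in the untagged control. Share and stretch differed between the 4 proteins (two-sided exact permutation over all ways of forming 4 pairs from the 8 libraries, p = 0.00952 for each, the smallest it allows; adjusted p = 0.0127). R95A enters both at background level, so this p is for all 4 proteins and not for WT, E93A and Q52A alone. The order of those 3 was not tested. The flank share gave the same exact permutation p, which is not read as a difference because R95A has little excess signal to divide. The height of the highest bin was 753 ± 398 times the median with WT (1034 and 472), 719 ± 39.1 with Q52A, 632 ± 243 with E93A and 6.68 ± 1.34 with R95A. That exact permutation test gave p = 0.133 for it, and all 14 ways with an F as large kept the R95A libraries together, so it does not bear on the distance of R95A from the rest. Pairs of proteins, 2 libraries against 2, cannot go below an exact p of 0.333 and are given as values.

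HA-ParB R95A lacked the wild-type accumulation. The core was 119-fold higher with WT than with R95A, and 72.0-fold without WT replicate 1 (fry median log2 of R95A minus WT -6.11, adjusted p = 1.61e-05). The first 10 kb on either side were also lower with R95A (-0.41 on the left, adjusted p = 0.0473; -0.72 on the right, adjusted p = 0.00438). At MXAN_7483, the gene with the largest deficit, R95A held 22.2 ± 0.261 RPM and WT 3787 ± 1358, a log2 difference of -7.30 ± 0.82 (SE; adjusted p = 0.0002 after background scaling). MXAN_7480, MXAN_7485, MXAN_7487, MXAN_7486, MXAN_7488, MXAN_7478, MXAN_7489, MXAN_7490 and MXAN_7492, all in the core, followed with log2 differences of -7.01 to -6.18. The gene parA held 17.1 ± 0.77 RPM with R95A against 606 ± 245 with WT.

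Of the 12 par_and_origin members, 3 were higher and 3 lower with R95A than with WT (adjusted over the list alone, 3 and 4; median log2 0.27, mean -1.05, adjusted p = 0.0014). After background scaling 3 were lower and none passed as higher (adjusted over the list alone, 4 lower; median -0.19, adjusted p = 0.0391). The lower ones were parA, gidA and gidB. The highly_transcribed list was higher as deposited (median 0.50, 18 of 23 members, adjusted p = 0.0121) but not after background scaling (median 0.03). Medians of the segregation_and_division and rRNA lists were 0.45 (adjusted p = 0.231) and 0.33 (adjusted p = 0.0778), and the first list passed the fry test for a change in either direction (adjusted p = 0.000296). The gene bacM was the segregation member that was lower, at 33.4 ± 5.56 RPM with R95A and 668 ± 278 with WT.

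Elsewhere R95A values exceeded WT values as deposited, by a median log2 of 0.45 over all bins. The gene with the largest such excess was aglS (gliding motility; 29.9 ± 7.56 against 16.1 ± 2.73 RPM, log2 0.84), which stood at 39.6 ± 12.7 RPM in the untagged control and no longer passed after background scaling (log2 0.34, adjusted p = 1), without WT replicate 1 (0.68) or without R95A replicate 1 (0.59). In total 4149 bins were higher and 26 lower. After background scaling limma called 0 higher and 17 lower, with 330 bins at an unadjusted p under 0.05 and 0 higher by edgeR with TMM. The higher count without single libraries was 6268 and 6246 (untagged 1 and 2) and 1 (R95A 2), and it was 0 (WT 1, Q52A 1, Q52A 2 or R95A 1; limma, 1501, 4345, 4344 and 3517 bins at an unadjusted p under 0.05; 3353 by edgeR on all libraries). The 26 lower bins became 6 without WT replicate 1, 11 without either Q52A library and 13 without either R95A library. The 17 of the scaled fit became 107 and 119 without untagged replicates 1 and 2, 6 without either Q52A library, 11 without either E93A library and 4 without either R95A library.

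The direct comparison of Q52A with E93A showed higher Q52A signal on both sides of the core and a longer reach on the left, where the stretch above 2 times the median extended 147 kb from the apex against 90 kb with E93A. On the right it extended 51 kb with both, and 48.5 kb (Q52A) and 47.5 kb (E93A) after division by R95A. With gaps of 10 kb closed it came to 144 kb (Q52A) and 189 kb (E93A), which are not read as reach of ParB. From 50 to 150 kb beyond the core the untagged control itself stood at 1.83 to 3.53 times its median. Over R95A, Q52A stood there at 1.12 to 1.23 times and E93A at 1.10 to 1.42 times. The largest differences between Q52A and E93A lay at distances of -78.9 to -69.1 kb from the apex, in the genes for exopolysaccharide synthesis wzx (MXAN_7416; 155 ± 3.91 RPM with Q52A, 10.2 ± 0.532 with E93A, log2 3.79 ± 0.19 SE), epsV (MXAN_7421; 265 ± 7.72 against 21.2 ± 0.0786), epsX (MXAN_7418), epsY (MXAN_7417), epsZ (MXAN_7415) and epsW (MXAN_7420), and in mobA (molybdenum cofactor synthesis; 79.9 ± 0.836 against 6.20 ± 0.165). To the right, gshB (glutathione synthase; 215 ± 3.54 against 19.9 ± 0.138), MXAN_0016 (an esterase) and MXAN_0014 were 17.4-fold to 17.7-fold higher after background scaling. From 10 to 50 kb beyond the core the median log2 difference was 2.52 on the left and 2.16 on the right (fry, adjusted p = 1.56e-05 and 1.36e-05). No shift in 1 direction was called over the core (-0.15, adjusted p = 0.61) or in the first 10 kb on the right (0.16, adjusted p = 0.561). That on the left passed only after background scaling (0.46, adjusted p = 0.195; 1.20, adjusted p = 0.0184).

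Some genes were lower with Q52A than with E93A on either scale. They were MXAN_0131 (a ClC chloride channel; 4.43 ± 0.289 against 28.8 ± 6.96 RPM, log2 -2.44, and -1.84 after background scaling), its neighbours MXAN_0130 and MXAN_0133, MXAN_3503 (a cupin protein; 5.14 ± 0.00304 against 28.0 ± 4.44) and MXAN_3505, MXAN_0290, MXAN_0293 and MXAN_0294, and MXAN_0526 and MXAN_0528 (an AcrB-family efflux transporter; 3.99 ± 0.0868 against 21.7 ± 2.71). The untagged control also held signal in these genes, such as 31.5 ± 3.89 RPM at MXAN_0130 and 10.1 ± 0.50 at MXAN_0528. In the par_and_origin list 5 members were higher and 3 lower with Q52A than with E93A (median 0.12, adjusted p = 0.0377), and 5 higher and none called lower after background scaling (median 0.86, adjusted p = 0.0191). In total 171 bins were higher and 6236 lower, and 214 and 153 after background scaling. The 6236 became 3617 and 3048 without Q52A replicates 1 and 2 and 2374 without E93A replicate 1. The scaled counts were 426 and 299 without untagged replicate 1 and 438 and 304 without untagged replicate 2. The lower one was 84 without either Q52A library and 74 without E93A replicate 2.

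Set against R95A, both Q52A and E93A stood out over the core and its flanks. Q52A exceeded R95A most at MXAN_7471 (egtB; 605 ± 14.2 against 6.97 ± 0.597 RPM, log2 6.25 ± 0.30 SE), MXAN_7474, gidA (481 ± 16.8 against 5.40 ± 1.00), MXAN_7473 (egtD), MXAN_7487, MXAN_7492, gidB, MXAN_7470, MXAN_7500 and MXAN_7469, with adjusted p of 1.4e-09 to 1.3e-06 after background scaling. E93A exceeded it most at MXAN_7488 (1637 ± 472 against 18.3 ± 1.45 RPM, log2 6.38 ± 0.71 SE), MXAN_7492, MXAN_7483, MXAN_7490, MXAN_7485, MXAN_7486, MXAN_7489, MXAN_7487, MXAN_7480 and MXAN_7474, with adjusted p of 8.6e-07 to 6.7e-05. Of the 12 par_and_origin members, 9 were higher with each protein on either scale. The other 3 were lower with each protein as deposited, and none was called lower after background scaling. None of the genes named as lower with Q52A than with R95A, such as pilH (log2 -2.02), clpS (-2.01) and MXAN_1086 (-2.08), passed after background scaling. Of those named as lower with E93A, only MXAN_6021 (a NifU-family protein, 4.33 ± 0.522 against 11.1 ± 0.281 RPM) did, at a log2 of -0.33 (limma, adjusted p = 0.035). Over all genes 22 were lower with Q52A and 11 with E93A after background scaling.

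As deposited, 195 bins were higher and 8840 lower with Q52A than with R95A, and 155 and 8462 with E93A. The scaled splits were 360 and 16, and 402 and 6. Leaving out untagged replicates 1 and 2 moved the scaled Q52A counts to 711 and 451, and to 723 and 465, and the E93A counts to 741 and 244, and to 749 and 269. The higher E93A count was 259 without E93A replicate 2. The 16 became 3 without either WT library, 8 and 7 without E93A replicates 1 and 2 and 9 without R95A replicate 2. The 6 became 1 without any single WT or Q52A library, 2 without E93A replicate 2 and 3 without R95A replicate 1. The 16 became 0 without Q52A replicate 1, Q52A replicate 2 or R95A replicate 1 (limma; 714, 736 and 694 bins at an unadjusted p under 0.05; 19 by edgeR with TMM on all libraries). The 6 became 0 without E93A replicate 1 or R95A replicate 2 (limma; 897 and 837 bins; 6 by edgeR with TMM on all libraries).

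**Figure D3:**
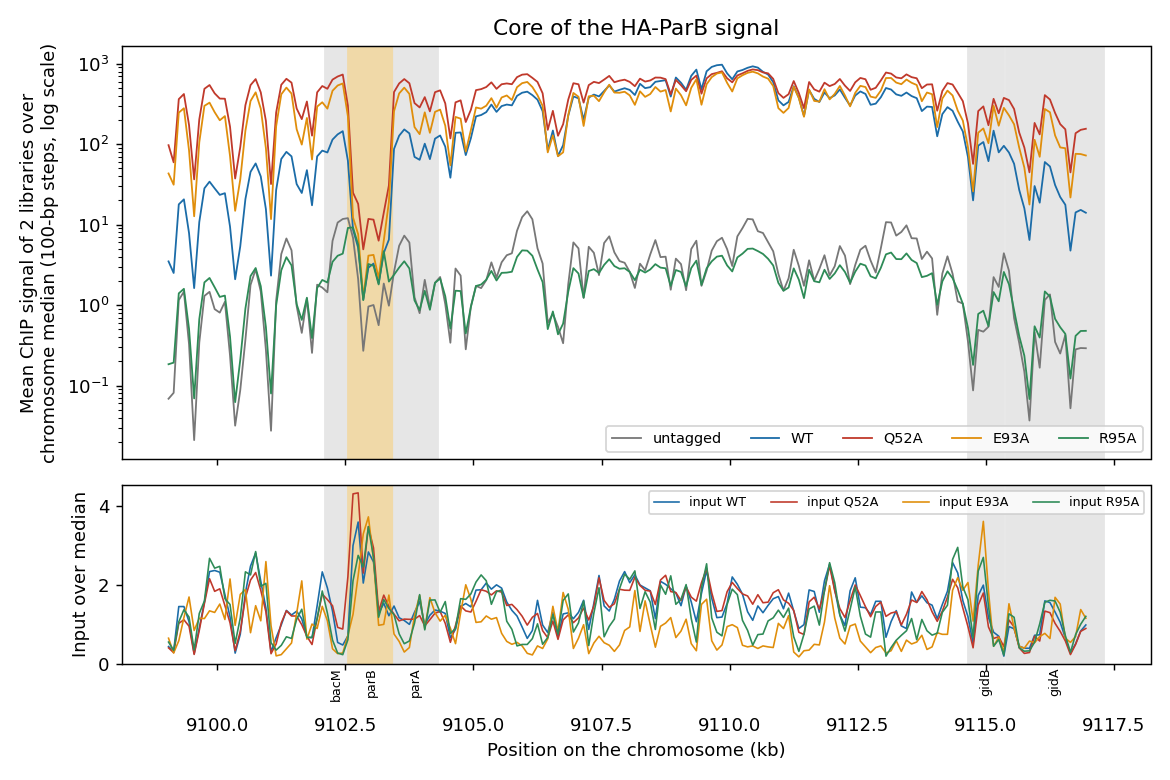
Level over the chromosome median across the core and 1 kb beyond it in 100-bp steps, by position in kb. The mean of the 2 libraries of each ChIP group is above (log axis) and the 4 inputs are below. The genes bacM, parB, parA, gidB and gidA are shaded. The signal of WT, Q52A and E93A is interrupted over parB, where the inputs rise to 2.20 to 2.56 times the median.

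Inside the core the signal was uneven, and parB itself (9102551 to 9103450) held little of it. With WT, parB averaged 54.9 ± 9.01 RPM between bacM at 668 ± 278 and parA at 606 ± 245. With Q52A the values were 107 ± 1.67, 1627 ± 49.8 and 1158 ± 38.7, and with E93A 96.7 ± 11.2, 1929 ± 425 and 1239 ± 263. Over the inner part of parB the signal was 0.0245 and 0.0516 times that of its flanks in the WT libraries, 0.0247 and 0.0240 times with Q52A, and 0.0160 and 0.0131 times with E93A. With R95A the inner part stood above its flanks, at 1.72 and 1.49 times, as in the inputs (1.72 to 2.24 times). In the untagged control it stood at 0.307 and 0.479 times. The tagged strains also carry HA-parB on an introduced plasmid, per the labels, so the reads of this gene need not come from the core alone.

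**Figure D4:**
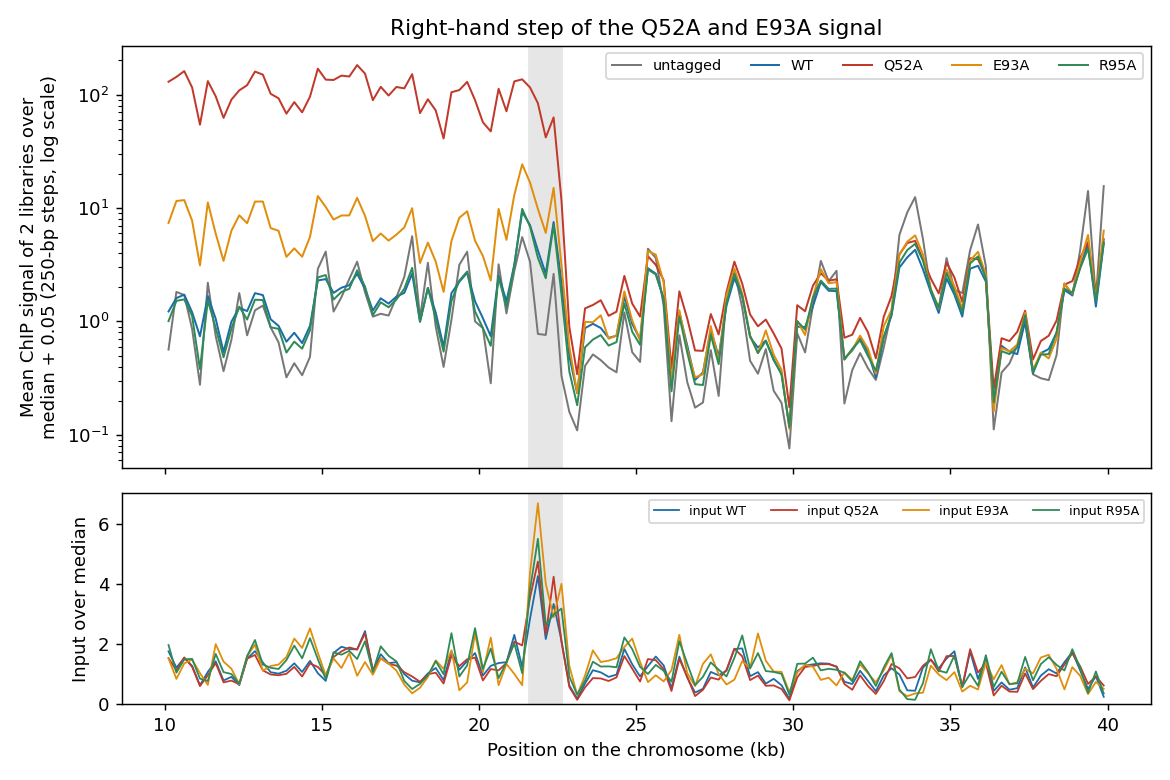
Level over the chromosome median (log axis, 250-bp steps, mean of 2 libraries plus 0.05) from 10 to 40 kb on the chromosome by position, with the 4 inputs below and the segment 21601 to 22650 shaded. The Q52A level falls from 98.3 and 96.5 times the median in the last 5 kb before 22500 to 1.43 and 1.40 times in the first 5 kb after it.

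On the right-hand side the Q52A and E93A signals dropped in a step near 22500, at the left end of MXAN_0019. MXAN_0018 (19551 to 21300) held 237 ± 8.94 RPM with Q52A, 30.3 ± 1.72 with E93A and 11.3 ± 0.11 with WT. MXAN_0019 (22451 to 24700) held 8.17 ± 0.602, 5.40 ± 0.229 and 6.04 ± 0.0766. The level in the last 5 kb before 22500 was 68.8 and 68.7 times that in the first 5 kb after it with Q52A and 6.39 and 6.68 times with E93A, against 3.05 and 2.43 times with R95A, 2.56 and 2.52 with WT and 2.83 and 2.30 in the untagged control. Beyond the step the E93A level was 1.44 ± 0.02 at 50 to 75 kb from the core and 2.37 ± 0.49 at 150 to 200 kb, against 1.31 ± 0.04 and 1.09 ± 0.02 with R95A and 1.83 ± 0.31 and 1.70 ± 0.29 in the untagged control. The segment 21601 to 22650 at this step lay above its flanks in all 4 inputs, at 2.69 to 3.6 times, and at 0.893 and 0.903 times in the untagged libraries. On the left flank Q52A still stood at 6.04 ± 0.13 times the median 100 to 150 kb from the core, against 1.32 with WT.

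**Figure D5:**
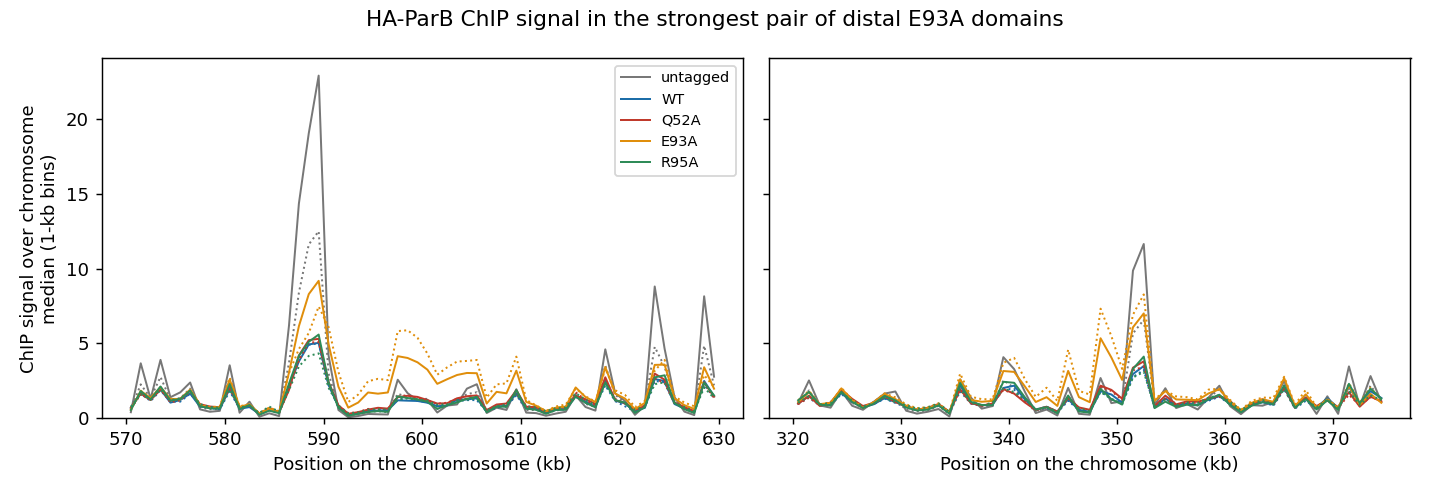
Level over the chromosome median in 1-kb steps around 590001 to 610000 and 340001 to 355000, by position in kb, for all 5 ChIP groups, with solid and dotted lines for replicates 1 and 2. E93A averages 2.99 and 3.20 times the median in these regions, R95A 0.975 and 1.34 times and the untagged control 1.08 and 2.15 times.

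Far from the core, broad low domains appeared with E93A. Over 590001 to 610000, which holds MXAN_0523 to MXAN_0534, the E93A level was 2.99 ± 0.65 and the R95A level 0.975 ± 0.02 (3.06-fold). Over 340001 to 355000 (MXAN_0286 to MXAN_0300) they were 3.20 ± 0.54 and 1.34 ± 0.09 (2.38-fold), with 2.15 ± 0.54 in the untagged control. A rule set after the data were seen took 5-kb bins over 300 kb from the apex that were higher with E93A than with R95A after background scaling (limma, adjusted p under 0.05, log2 of at least 0.5) and merged those within 10 kb of each other. It gave 7 such domains, in which the median fold over R95A was 0.998 for WT and 1.07 for Q52A.

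The inputs were nearly flat in comparison. The mean input signal within 500 kb of the apex was 1.11 (WT), 1.07 (Q52A), 1.22 (E93A) and 1.41 (R95A) times that on the opposite side of the chromosome, and in the untagged ChIP libraries this ratio was 1.26 and 1.20. At parB the inputs stood at 2.13 (WT), 2.65 (Q52A), 1.95 (E93A) and 2.07 (R95A) times their medians. Each is a single library, so none of these ratios has a replicate.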

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

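Of the tests in this part, those of mapping and of extra DNA at the right-hand step, both tests of the parB gap and both tests of background peaks in the E93A domains were chosen only after the results were seen; those of a rearranged chromosome, of the E93A input and of single E93A libraries were set before. The inner part of parB was chosen at the same late stage.

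The input libraries, which have no replicates and were not tested as groups, exceeded the untagged ChIP control at various places, of which 2 were picked for a closer look after their values were seen. The segment 21601 to 22650, which lies beyond MXAN_0018 and reaches into the left end of MXAN_0019, was chosen as raised in all 4 inputs. It stood at 2.69 (WT), 3.34 (Q52A), 3.6 (E93A) and 2.87 (R95A) times its flanks in the inputs, against 0.893 and 0.903 times in the untagged libraries. The inner part of parB stood at 2.20 (WT), 2.56 (Q52A), 2.46 (E93A) and 2.36 (R95A) times the chromosome median in the inputs, against 0.803 and 0.998 times in the untagged libraries. The untagged strain has no input of its own here, so inputs and control are different kinds of library.

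The first pattern is the right-hand step of the Q52A and E93A signals at 22500 (E93A stood above R95A again 150 to 200 kb from the core). Sequence that reads do not map to is argued against, since the inputs stood at 0.961 to 1.14 times the median 1 to 21 kb beyond it. A rearranged chromosome that carries the adjoining sequence to a place more than 300 kb from the apex is argued against too, because no 5-kb bin there had a Q52A over R95A ratio above 0.0407 of that before the step (1.65 against 40.6). Extra DNA joined to the chromosome at this place in the tagged strains remains a candidate explanation. The ratio of the segment to its flanks in R95A was 3.67 times that in the untagged control. That value does not show where such DNA lies, how long it is or whether it produces the step. The ratios of the inputs do not bear on it because the segment was chosen on them. A barrier to ParB that lies in the sequence itself or in bound proteins was not tested, since all tagged strains share the sequence.

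The next pattern is the set of E93A domains far from the core. Background peaks shared with the untagged control are argued against for most of them, as the median log2 of E93A over the control was 0.72 in the domains (0.95 over R95A) and both E93A libraries exceeded both untagged ones in 6 of 7; in the domain 7920001 to 7930000 the E93A level was 0.812 times the control, so background stays open there. A shape shared with the input is argued against by a median log2 of -0.0199 for the E93A input over the R95A input, and an origin in 1 of the 2 E93A libraries by bins chosen on one pair of libraries, which had a median log2 of at least 0.81 in the other pair (1.13 where chosen). A difference of the E93A protein itself, which the design names, may account for most of these domains. It is a hypothesis found and tested on the same libraries. By the labels each protein comes from 1 strain, so the exchange cannot be told apart from other differences of the E93A strain.

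The last pattern is the gap over parB in the signal of WT, Q52A and E93A. Sequence that reads do not map to is argued against by inputs at 2.20 times the median or more over the inner part of the gene. Copies of parB that lie only away from the parS cluster in these strains stay open. The inputs stood at 1.72 to 2.24 times the flanks of the gene, but the introduced HA-parB would raise them in any case. Over the inner part WT stood at 2.81 and 2.61 times the median and E93A at 3.09 and 4.03, near R95A at 3.02 and 2.47. Q52A stood higher, at 9.63 and 9.96. Such low levels go with copies away from the core, but a protected parB inside it would also give them, so they do not decide. The untagged control had a weaker step at the borders of the gene (2.70 to 6.89 times, against 14.9 to 89.0 in the 6 libraries), so part of the shape need not depend on the tagged protein. Protection of parB from binding by another means was not tested.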

How the results depend on the processing

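Of the tests in this part, edgeR with TMM, background scaling with a library left out, gaps of 10 kb closed and division by the R95A libraries were chosen only after the results were seen.

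With 2 libraries per group, single libraries decide many counts away from the core, and a group left with 1 library is assumed to vary like the others. Each summary value was followed over the alternatives and left-out libraries that were run for it. The fry tests were run only as deposited, after background scaling and under the replicate block. Of these values, 712 kept their direction and side of the threshold, stayed within 1.5 times (counts) or moved within the SD (profile measures). A further 176 moved more, 24 lost and 2 gained a call, and 6 changed sign. Background scaling gave 22 of the lost calls and all 6 changes of sign. Among single genes the numbers were 1704 kept, 134 lost, 21 gained and 1 of changed sign. Except where a reason is given, the cause was not tested. As no genome sequence was used here, the core drawn from parS matches and parS matches without a mismatch were not run. Replicates differed by more than counting error in every group (chi-square per degree of freedom 3.18 to 137), so depth was not the largest part of the spread.

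Background scaling removes the shift of the medians by construction. Genes higher and lower became 306 and 9 (Q52A minus WT), 312 and 6 (E93A minus WT), 336 and 22 (Q52A minus R95A) and 356 and 11 (E93A minus R95A). For Q52A minus E93A 132 genes were lower. For R95A minus WT limma called 0 genes higher, with 279 genes at an unadjusted p under 0.05; edgeR was not run on genes. In kb, 1 was enriched with R95A. The higher and lower kb were 338 and 6 (Q52A minus WT), 368 and 4 (E93A minus WT), 360 and 16 (Q52A minus R95A) and 402 and 6 (E93A minus R95A), and 153 were lower for Q52A minus E93A. For R95A minus WT limma called 0 kb higher and 17 lower, with 330 bins at an unadjusted p under 0.05 and 0 higher by edgeR with TMM. The core median log2 of Q52A minus WT turned to 1.04 and that of the right 10 to 50 kb of R95A minus WT to -0.12. The left 10 kb of Q52A minus E93A gained a call at 1.20. The 10 to 50 kb flanks of R95A minus untagged lost theirs at 0.0485 (left) and 0.00678 (right). The gene recF turned to 0.10 for Q52A minus WT.

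Under the same scaling, list medians that lost their call were, for highly_transcribed, -0.28 (Q52A minus untagged), -0.19 (E93A minus untagged), -0.0883 (Q52A minus WT), -0.0184 (E93A minus WT), 0.0335 (R95A minus WT), -0.0511 (Q52A minus E93A), -0.10 (Q52A minus R95A) and -0.0687 (E93A minus R95A). For rRNA they were -0.68 (WT minus untagged), -0.82 (Q52A minus untagged), -0.64 (E93A minus untagged), -0.12 (Q52A minus WT) and -0.14 (Q52A minus E93A), and the sign turned to 0.00837 (Q52A minus R95A) and 0.15 (E93A minus R95A). For segregation_and_division they were 0.0875 (WT minus untagged), -0.0123 (Q52A minus untagged), 0.00638 (R95A minus untagged), -0.0940 (Q52A minus WT), -0.0713 (Q52A minus E93A), -0.13 (Q52A minus R95A) and -0.0606 (E93A minus R95A). The par_and_origin medians turned to -0.00112 (R95A minus untagged) and -0.19 (R95A minus WT).

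A pseudocount of 0.1 RPM enriched 116 kb with WT and 1625 with R95A, and 5 RPM enriched 2 with R95A. With no filter on low values 2384 kb were higher for R95A minus WT and 4 lower for E93A minus WT. Bins of 5 kb enriched 5 kb with R95A, and gave 265 kb higher and 5535 lower for E93A minus WT and 7270 higher for R95A minus WT. Bins of 500 bp enriched 520 kb with R95A, and gave 21 kb lower for E93A minus WT and 2106.5 higher for R95A minus WT. Without the trend 21 kb were lower for E93A minus WT and 2529 higher for R95A minus WT. Division by the own input gave 720 kb higher and 4215 lower for E93A minus WT and 440 higher for Q52A minus E93A. On whole reads edgeR enriched 59 kb with WT and 1498 with R95A, and called 559 lower for E93A minus WT. With TMM, set against background scaling, it enriched 179 kb with WT, 499 with Q52A and 80 with R95A and called 26 lower for R95A minus WT. It called 0 kb lower for E93A minus WT (801 bins at an unadjusted p under 0.05 in either direction; 4 by limma).

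The stretch was 51 kb (WT) and 211.5 kb (Q52A) above 1.5 times the median. Above 4 times it was 25.5 kb (WT), 196 kb (Q52A) and 119 kb (E93A). With gaps of 10 kb closed it was 61, 425 and 367 kb, and after division by R95A 28.5, 197.5 and 141 kb. With the mean of bins over 500 kb away as background it was 31.5 kb (WT) and 130.5 kb (E93A), the height with Q52A was 619 and the flank share 0.411% (WT) and 39.9% (R95A). With the untagged mean subtracted the stretch was 30, 196 and 136.5 kb, the share near the apex 71.0% (Q52A) and 2.25% (R95A), the height with R95A 3.83 and the flank share 0.403% (WT) and 85.2% (R95A).

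The sample numbers share only a number: differences of sample 2 from sample 1 correlated between groups at -0.35 to 0.87, and 5 of 10 pairs of groups lay at or below 0.1. A replicate block left the counts of enriched kb and of kb and genes that differ between proteins within 1.5 times. For WT minus untagged with no minimum log2, the bins higher went from 333 to 582 and the genes higher from 304 to 458. Under this block the left 10 kb of R95A minus WT (-0.41, adjusted p = 0.058) and the par_and_origin list of Q52A minus E93A (0.12, adjusted p = 0.0536) lost their call. The left 10 to 50 kb of R95A minus WT (0.34, fry, adjusted p = 0.0371) and parA (MXAN_7477) for Q52A minus WT (0.99, limma, adjusted p = 0.0424) gained one. No other fry call for a shift in 1 direction changed, nor did that of a gene named per contrast or of a par_and_origin member against WT. Counts of list members did move, such as segregation_and_division members higher for R95A minus WT, from 7 to 9. For a change in either direction, the rRNA list gained a call for Q52A minus E93A (fry, adjusted p = 0.0265) and for E93A minus R95A (fry, adjusted p = 0.0262).

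Leaving out each library in turn gave 23 to 266 kb enriched with WT and 1 to 2208 with R95A. It gave 6 to 27 kb lower for R95A minus WT and 2374 to 7442 for Q52A minus E93A. For E93A minus WT 0 to 5086 kb were lower and for R95A minus WT 0 to 6268 higher (limma, 447 bins at an unadjusted p under 0.05 for the first 0 and 1501 to 4345 for the others; 559 and 3353 by edgeR on all libraries). In genes the ranges were 2056 to 6037 lower for Q52A minus E93A, 0 to 4346 lower for E93A minus WT (limma, 434 and 660 genes at an unadjusted p under 0.05 where 0) and 0 to 5378 higher for R95A minus WT (1405 and 3236 where 0). After background scaling they were 22 to 69 kb enriched with WT and 1 to 7 with R95A. Higher kb were 220 to 550 (E93A minus WT), 183 to 438 (Q52A minus E93A), 251 to 723 (Q52A minus R95A) and 259 to 749 (E93A minus R95A). Lower kb were 4 to 119 (R95A minus WT) and 74 to 304 (Q52A minus E93A). Lower kb also ranged from 0 to 45 (Q52A minus WT), 0 to 148 (E93A minus WT), 0 to 465 (Q52A minus R95A) and 0 to 269 (E93A minus R95A), where limma had 493 to 897 bins at an unadjusted p under 0.05 at each 0 and edgeR with TMM on all libraries called 9, 0, 19 and 6.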

Other observations

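The test of gene orientation in this part was set before its result was seen; the places described were picked after their values were seen, and no further test was made of them.

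On the right-hand side, 150 to 200 kb beyond the core, the E93A signal stood at 2.37 ± 0.49 times the median (n = 2). It was 1.07 with WT, 1.21 with Q52A, 1.09 with R95A and 1.70 ± 0.29 in the untagged control. Further from the core, 3 more of the broad E93A domains are described here. Over 1870001 to 1885000 (MXAN_1592 to MXAN_1603) the E93A level was 1.70 ± 0.32 and the R95A level 0.834 ± 0.04. Over 8610001 to 8625000 (MXAN_7035 to MXAN_7048) they were 1.79 ± 0.27 and 0.952 ± 0.03, and here Q52A also stood above R95A, at 1.3 ± 0.03. Over 7265001 to 7275000, with acsA and sodC (superoxide dismutase), they were 2.09 ± 0.38 and 1.14 ± 0.04.

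The fixed lists were also set against the untagged control. After background scaling the segregation_and_division list had median log2 differences of 0.09 (WT), -0.0123 (Q52A), 0.10 (E93A) and 0.00638 (R95A), and none passed the fry test for a shift in 1 direction (adjusted p 0.489, 0.859, 0.174 and 0.893). The fry test for a change in either direction did pass with each protein (adjusted p 0.000428, 2.13e-05, 2.01e-05 and 0.0301); the list includes bacM, which lies in the core. For the highly_transcribed list they were -0.19, -0.28, -0.19 and -0.21 (adjusted p 0.346, 0.174, 0.244 and 0.467), with a change in either direction called for Q52A (adjusted p = 0.0369) and not for the other proteins. The condensin gene smc held 5.75 ± 1.09 RPM with WT and 5.75 ± 0.316 in the control, and rpoB, which encodes an RNA polymerase subunit, held 9.82 ± 1.43 and 12.4 ± 0.256.

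The untagged control had peaks of its own. Its highest bin, 8710001 to 8711000 over MXAN_7134 and MXAN_7135, stood at 30.2 ± 13.9 times the median. It stood at 7.10 with WT, 7.42 with Q52A, 10.2 with E93A and 6.68 with R95A, and it was also the highest bin of both R95A libraries. The inputs there stood at only 0.0519 (WT), 0.328 (Q52A), 0.179 (E93A) and 0.114 (R95A) times their medians. The next highest bins of the control, at 3382001 (MXAN_2894), 8214001 (MXAN_6679), 547001 (MXAN_0487 and MXAN_0488) and 1439001, stood at 26.6 to 27.2 times the median.

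One hypothesis on the left flank was that the Q52A and E93A signals decline faster across genes transcribed towards the core. With Q52A the mean log2 drop per kb was 0.0132 ± 0.34 (SD between genes) across 29 such genes and -0.0717 ± 0.20 across 23 transcribed away from it. The difference was 0.0849 (two-sided permutation test with 100000 draws, p = 0.294). With E93A the means were 0.0294 ± 0.25 and -0.0275 ± 0.23, and the difference 0.0569 (same permutation test, p = 0.415). A negative mean is a rise away from the core, so the genes transcribed away showed no decline by this measure. The flank itself did decline: Q52A over R95A fell from 136 at 10 to 20 kb from the core to 4.69 at 100 to 150 kb. E93A over R95A fell from 33.2 to 1.83 between the same bands. The measure within genes thus missed this decline in the genes transcribed away and cannot decide the question. Differences of this size between the orientations also lie within the spread between genes.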
